A study of Arabidopsis thaliana with 9 samples.

How the data were processed

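RNA of whole plants at growth stage 1.04 was measured in 9 samples, 3 each of the wild-type control, line774 and line1135. Plants were sown at 50 seeds per plate on a medium with iron citrate and sucrose, per the labels' protocols. RNA was extracted with a column kit, amplified from the 3' end, labelled with biotin and hybridised to ATH1 arrays, 1 per sample. The deposited values are linear intensity per probe set, computed with MAS5 and GCOS, per the submitters' processing notes, whose versions are not given in the sources used here. The deposited intensity columns each had a 2% trimmed mean near 100, so each array had been scaled by 1 factor. No detection calls were used here. Groups and replicate numbers came from the sample titles, and no 2 arrays held identical values.

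From these values, 64 control probe sets of 22810 were left out, and the remaining 22746 were tested without a filter on low signal. Values were transformed to log2(signal + 16). A model with 1 mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), which leaves 6 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all probe sets in each comparison, and a call needed an adjusted p under 0.05 and a change of at least 2-fold. The 27 Bacillus control probe sets, whose highest signal per array lay between 5.36 and 13.4, served as the background. Where all arrays of a group were at or below it, the fold is given as "at least" the brighter group's mean log2 signal against the dimmer group's mean log2 of that background. Of the tested probe sets, 2797 were at or below background on all 9 arrays.

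Probe sets were named through the platform annotation given with the series. It named 1 gene for 13513 probe sets, several for 503 and none for 8730, which are unnamed here and not without a gene. No gene was named from a probe set with several. Of those with 1 gene, 13436 matched a locus of the RefSeq gene table of the TAIR10.1 assembly, 12443 of them protein coding and 989 of a pseudogene type (923 pseudogene and 66 transcribed pseudogene). Of these 989, 798 end in _at and 191 in _s_at or _x_at. No coordinates are given, since the arrays name no build. The planned class of transposable elements matched 0 probe sets, so the pseudogene class was used in its place, a choice made after the data were seen. Its enrichment among calls was tested by two-sided Fisher exact tests, with probe sets of 1 matched gene as background and 12 tests in the family.

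Named genes followed a rule fixed before the data were examined. It took the 10 largest increases and 10 largest decreases per comparison among called probe sets with 1 gene and non-overlapping arrays. It added up to 4 called members per gene list (or the 2 with the lowest p) and the 6 strongest shared changes in each direction. The brightest probe set stood for a gene. The rule also named 2 silencing genes that are not named by the annotation used here, and these are not analysed here. Gene lists for silencing regulators, methylation-silenced genes, the methionine cycle, salicylic acid, jasmonate, cold and abscisic acid, heat shock, photosynthesis, flavonoids, flowering, DNA damage, cell cycle, clock, root, seed and senescence were also fixed beforehand. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01 and with an estimated one, adjusted over 24 tests. A list of iron deficiency genes, the pseudogene class, the plastid-encoded genes and gene families sharing a symbol with at least 8 members were added after the data were seen and adjusted over 96 tests.

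Overlap between the lines was set against 100 simulations of unchanged groups sharing the controls. On simulated data for line774 against the control, with 22746 probe sets and 50 changed at each size, the test recovered 100% at a log2 change of 2 or -2, 88% at 1.2 and 94% at -1.2, and called 0 unchanged probe sets. The changed probe sets were drawn only from those with a control signal well above background, with independent normal noise. Recovery of changes from a low control signal was not measured. Alternatives tried were offsets of 1 and 64, filters at the 25th and 50th percentile of mean signal, quantile normalization, median scaling, no intensity trend, fits of only the compared groups, the replicate number as a block, leaving out probe sets shared between loci, no minimum fold, an adjusted p under 0.01, and leaving out each array in turn. Leaving out probe sets near background was added after seeing the data. Figures were drawn with matplotlib 3.10.9.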

Results

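Whole Arabidopsis thaliana plants of 2 mutant lines, line774 and line1135, were compared with a wild-type control on the Affymetrix ATH1 array, a one-colour array that reads each transcript with a set of short probes (a probe set). Plants had grown for 17 days on plates at 21 °C under 16 h of light and 8 h of darkness. Each of the 3 groups had 3 arrays, 9 in all, and this number limits the precision of every value given here. The series title names epigenetic mutants, and the question addressed was which transcripts differ between each line and the control, and between the lines. The labels used here do not give the mutated gene of either line, and a label naming a T-DNA insertion mutation stands on all 9 samples, control included, so the targeted gene could not be checked. Nothing in the labels says whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Signals had been scaled to a common mean per array, with group medians of 35.8 ± 0.322 in the control, 36.9 ± 0.586 in line774 and 36.3 ± 0.914 in line1135 (SD, n = 3). Rank correlations between arrays of a group were 0.964 to 0.975, those between control and mutant arrays 0.934 to 0.955, and those between the mutant lines 0.957 to 0.965.

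Changes below are log2 differences of signal + 16 with their standard errors, from 3 arrays per group, and adjusted p-values are limma's. A probe set was called when its adjusted p was under 0.05 and its change at least 2-fold. The offset understates the change of transcripts with low signal. Probe sets whose only annotated locus has a pseudogene type in the RefSeq gene table are called pseudogene class here. The tables used here have no class for transposable elements, and a planned search for transposon words in gene names matched 0 probe sets.

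In line774, 87 of the 989 pseudogene-class probe sets were called higher and 900 were not called (camera adjusted p = 0.000683, and adjusted p = 0.606 with an estimated correlation). The 10 largest increases on the offset scale, among probe sets with 1 named gene, were all of this class. AT3G30396 went from a signal of 2.43 ± 2.47 in the control to 2466 ± 199 (SD, n = 3), at least 410-fold higher, and AT2G12980 from 0.426 ± 0.334 to 2171 ± 139, at least 362-fold higher. AT2G13160 (7.07 ± 0.18), AT2G12300 (6.75 ± 0.13), AT2G12240 (6.74 ± 0.14), AT2G10640 (6.65 ± 0.08) and AT1G33130 (6.43 ± 0.16) were also among the 10. These values hold only for the offset used. Over all alternatives that of AT2G13160 ran from 5.38 to 9.21 and that of AT2G12240 from 5.04 to 8.93. The other 3, with controls at or below background, were AT2G13870 (at least 155-fold higher), AT3G47320 (at least 163-fold) and AT3G31955 (at least 146-fold). The gene QQS, an orphan gene that affects starch content and whose expression varies with its DNA methylation, rose by 3.04 ± 0.08 from a signal of 145 to 1298. AT2G04770, listed as a CACTA-type transposase gene, was at least 133-fold higher, with a signal of 2.35 in the control, at or below background, and 795 in line774. Of the genes named in this paragraph, only AT3G47320 and QQS were read by _at probe sets. The others were read by _s_at or _x_at probe sets, which share probes with related loci, so they may not be separate loci that each rose.

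The 10 largest decreases in line774 among probe sets with 1 named gene were in protein-coding genes. OCT1, an organic cation and carnitine transporter, fell from a signal of 391 ± 58.1 to 9.37 ± 7.24, a log2 change of -4.04 ± 0.21 (adjusted p = 6.33e-07). Its line774 signal was near background, and over all alternatives the change ran from -5.68 to -2.63. HIS1-3, a linker histone induced by drought, changed by -2.02 ± 0.18, and AT1G19200 went from a signal of 156 ± 7.77 to 5.77 ± 4.42. The others with the largest decreases were AT2G20670 (-3.14 ± 0.35), AT3G07350 (-2.50 ± 0.18), AT1G08310 (-2.49 ± 0.17), AT5G20790 (-2.47 ± 0.20), AT1G64590 (-2.07 ± 0.19), AT1G09500 (-2.02 ± 0.12) and AT1G23390 (-1.94 ± 0.20). COR15A, a cold-regulated chloroplast protein, fell by 1.52 with a standard error of 0.34 (adjusted p = 0.0149). Without control replicate 1 its adjusted p was 0.0654, and over all alternatives it lay between 0.00179 and 0.0654.

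In total, 233 probe sets were higher and 223 lower in line774 than in the control, of 22746 tested. The pseudogene class made up 87 of those higher and 2 of those lower. This was 8.80% of its 989 probe sets against 0.707% of the 12447 other probe sets with a matched single gene, an odds ratio of 13.5 (95% interval 9.87 to 18.6, two-sided Fisher exact test, adjusted p = 1.83e-51). The Fisher tests treat probe sets as independent, which those sharing probes are not. Many of these probe sets end in _s_at or _x_at, which share probes with related loci, so their signals may not belong to the named locus alone. Among probe sets ending in _at, 27 of the pseudogene class were called higher, with an odds ratio of 5.00 (95% interval 3.10 to 7.84). The pseudogene class took 0.0948 ± 0.0118% of the summed signal in the control and 0.980 ± 0.0916% in line774 (SD, n = 3). At the offset of 16, a probe set with a control signal under 16 cannot be called lower, even if its signal is lost entirely. With so small a share of the control signal, most of the class could not be called lower. The counts depended on the offset, with 481 higher and 364 lower at an offset of 1, and 102 and 107 at an offset of 64.

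In line1135, the 10 largest increases on the offset scale, among probe sets with 1 named gene, were also all of the pseudogene class. AT3G30396 reached a signal of 3278 ± 78.6 (SD, n = 3), at least 547-fold above the control. AT2G12240 (7.24 ± 0.14), AT2G12300 (7.24 ± 0.13), AT2G10640 (7.16 ± 0.08), AT2G13160 (6.89 ± 0.18), AT1G33130 (6.42 ± 0.16) and AT4G03790 (6.12 ± 0.14) were also among the 10, as were, with controls at or below background, AT2G12980 (at least 246-fold higher), AT4G05640 (at least 289-fold) and AT3G47320 (at least 224-fold). The log2 values hold only for the offset used. Over all alternatives that of AT2G12240 ran from 5.53 to 9.44 and that of AT2G13160 from 5.21 to 9.03. QQS rose by 3.02 ± 0.08, to a signal of 1287, and AT2G04770 was at least 195-fold higher, with a signal of 1187. Here only AT4G05640, AT3G47320 and QQS were read by _at probe sets, and the others by _s_at or _x_at probe sets, which share probes with related loci.

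OCT1 fell in line1135 to a signal of 2.85 ± 1.69 (SD, n = 3), at least 42.0-fold below the control, and HIS1-3 changed by -2.25 ± 0.18. AT1G19200 (-2.99 ± 0.17), AT5G20790 (-2.39 ± 0.20) and AT1G08310 (-2.29 ± 0.17) were again among the largest decreases. AT4G22490 (-2.55 ± 0.20), AT5G39520 (-2.19 ± 0.24), COR15A (-2.18 ± 0.34), ChiC, a chitinase (-2.16 ± 0.16), and GAT1_2.1, a glutamine amidotransferase-like protein (-2.15 ± 0.17), completed the 10.

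In total, 242 probe sets were higher and 278 lower in line1135 than in the control. The pseudogene class made up 148 of those higher and 1 of those lower, which was 15.0% of the class against 0.426% of the other probe sets (odds ratio 41.1, 95% interval 29.6 to 57.9, two-sided Fisher exact test, adjusted p = 2.33e-124). The other 840 of the class were not called, and camera gave adjusted p = 7.15e-12, and adjusted p = 0.198 with an estimated correlation. Among _at probe sets, 61 of the pseudogene class were higher (odds ratio 21.2, 95% interval 14.2 to 31.9). The class took 1.57 ± 0.00656% of the summed signal (SD, n = 3). As in line774, most of the class could not be called lower, given the offset and its low control signal. At an offset of 1 the counts were 501 higher and 490 lower, at an offset of 64 they were 111 and 113, and without probe sets that share probes between loci 146 were higher.

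**Figure D1:**
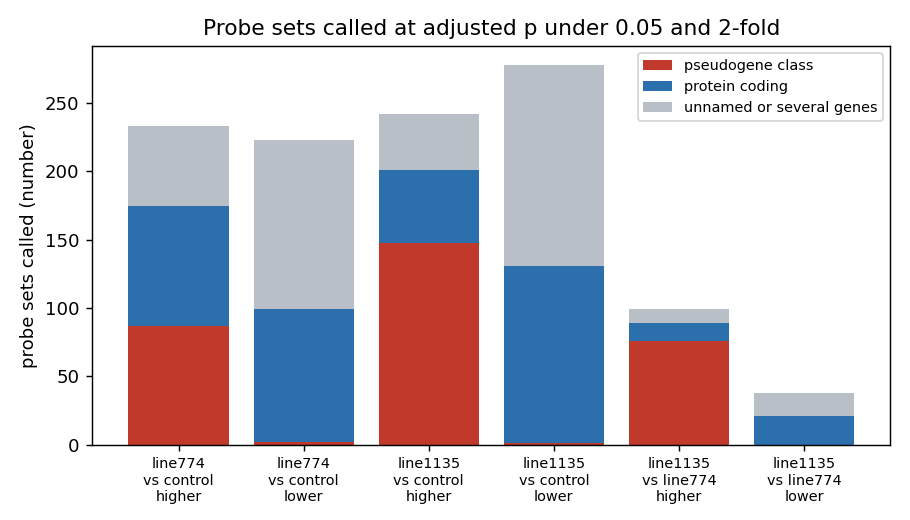
Number of probe sets called higher or lower in each of the 3 comparisons, stacked by the type of the annotated gene, with the vertical axis starting at 0. The pseudogene class supplied 87, 148 and 76 of the probe sets called higher, and 2, 1 and 0 of those called lower. Probe sets with a signal under 16 in the group compared against could not be called lower.

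Together, 133 probe sets were higher in both lines, 84 of them of the pseudogene class, and 160 were lower in both, 1 of them of that class. Among those higher in both were AT3G30396, AT2G12240, AT2G12300, AT2G10640, AT2G13160 and AT2G12980, all read by _s_at or _x_at probe sets. Among those lower in both were OCT1, AT1G19200, AT5G20790, AT1G08310, AT3G07350 and HIS1-3. AT3G07350 changed by -2.07 ± 0.18 in line1135. No probe set was called in opposite directions, where independent lists would give 5.22. Both lines were compared with the same controls, so chance overlap lies above that of independent comparisons. Unchanged groups simulated against those controls gave at most 0 shared increases and 1 shared decrease, but these groups were simulated without effects, so this is not a chance value for lists of the observed sizes. Independent lists of these sizes would share 2.48 and 2.73. The correlation of the changes across probe sets, which are not independent replicates, was 0.809, against 0.500 in the simulation. Their covariance was 0.139 against 0.0101, a difference of 0.129. The 3 controls are too few to split, so part of the excess may come from the shared controls.

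**Figure D2:**
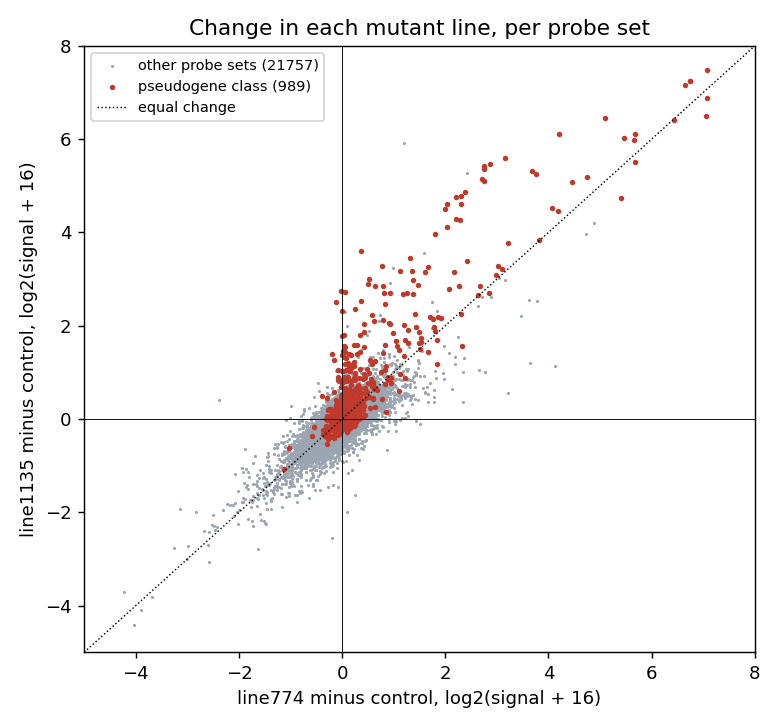
Log2 change of each of the 22746 probe sets in line774 (horizontal axis) and line1135 (vertical axis) against the control, on the log2(signal + 16) scale, with the 989 pseudogene-class probe sets in red and equal change as a dotted line. The 76 pseudogene-class probe sets called higher in line1135 than in line774 lie above the dotted line, and 0 were called lower. Probe sets with a line774 signal under 16 could not be called lower.

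Of the 99 probe sets higher in line1135 than in line774, 76 were of the pseudogene class. AT1G59930, annotated as protein coding but read by an _x_at probe set, had a signal of 6.25 ± 3.31 in the control, 36.1 ± 13.4 in line774 and 1332 ± 291 in line1135 (SD, n = 3), a difference between the lines of 4.71 ± 0.20 (adjusted p = 1.16e-06). AT1G36590 was at least 18.8-fold, AT4G08680 at least 10.2-fold, AT2G05470 at least 10.3-fold and AT2G24930 at least 8.44-fold higher in line1135 than in line774. AT1G36240 (2.84 ± 0.11), AT3G47260 (2.67 ± 0.21), AT2G14130 (2.61 ± 0.15), AT2G06430 (2.59 ± 0.24) and AT3G32900 (2.58 ± 0.25) were also higher in line1135. Of the genes named so far in this paragraph, only AT1G36240 and AT2G24930 were read by _at probe sets. SQN, a cyclophilin chosen after its values were seen, had a signal of 62.3 ± 6.65 in the control, 140 ± 31.4 in line774 and 725 ± 97.0 in line1135.

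Of the 38 probe sets lower in line1135 than in line774, AT1G20400 had a signal of 2.02 ± 2.31 in the control, 303 ± 66.1 in line774 and 23.7 ± 1.88 in line1135 (SD, n = 3), a difference of -2.99 ± 0.16. AT5G24240 (-2.66 ± 0.21), AT4G22490 (-2.36 ± 0.20) and AT3G16670 (-2.08 ± 0.23) were lower too. So were AT4G33720 (-2.44 ± 0.48), AT3G29970 (-1.61 ± 0.32), AT3G61930 (-1.60 ± 0.35), AT5G19890 (-1.50 ± 0.28), AT3G13610, a coumarin synthesis enzyme (-1.41 ± 0.24), and OSM34, an osmotin-like protein (-1.30 ± 0.21), but each of these 6 lost its call when some single array was left out. The call of OSM34 was lost without line1135 replicate 3, and that of AT3G13610 without line774 replicate 2 or line1135 replicate 1. The calls of AT4G33720, AT5G19890 and AT3G29970 were lost without replicate 1 or 2 of line774 or replicate 1 or 3 of line1135, that of AT3G29970 also without control replicate 3, and that of AT3G61930 without any array but line1135 replicate 2. Over all alternatives, adjusted p reached 0.118 for AT4G33720, 0.12 for AT3G29970, 0.137 for AT3G61930, 0.0918 for AT5G19890, 0.0677 for AT3G13610 and 0.0507 for OSM34.

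In total, 99 probe sets were higher and 38 lower in line1135 than in line774. The pseudogene class made up 76 of the 99 and 0 of the 38 (odds ratio for the higher 79.6, 95% interval 43.6 to 157, two-sided Fisher exact test, adjusted p = 1.68e-72), and 26 of the 76 were _at probe sets. For the class, camera gave adjusted p = 7.92e-10, and adjusted p = 0.198 with an estimated correlation. Without probe sets that share probes between loci, 44 probe sets were higher in line1135, 26 of them of the class. At an unadjusted p under 0.05, limma gave 1548 higher and 1829 lower probe sets of all classes. The count of 38 fell to 22 without line774 replicate 2 and to 25 without line1135 replicate 1 or line1135 replicate 3. Of the 109 probe sets called higher in line1135 and not in line774, 60 differed between the lines in the direct test, and of the 100 called higher in line774 and not in line1135, 19 did. For decreases these were 9 of 118 in line1135 and 3 of 63 in line774.

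**Figure D3:**
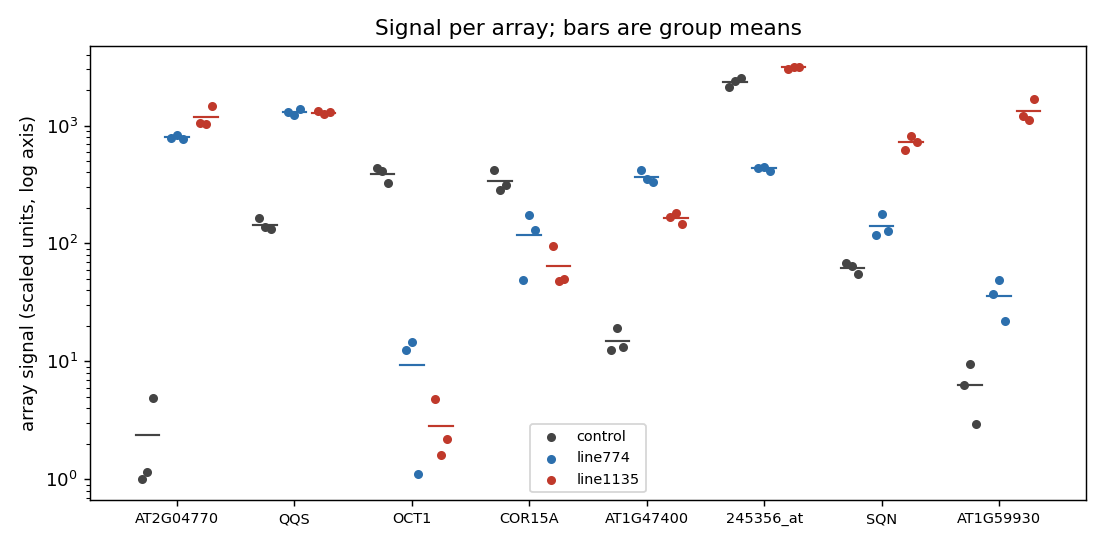
Signal of 8 transcripts on each of the 9 arrays (points) with the group means (bars), on a log axis in the scaled units of the arrays. AT2G04770 and QQS lie higher and OCT1 lower in both lines than in the control, while SQN, AT1G59930 and an unnamed probe set differ between the lines.

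Among the gene lists fixed before the data were examined, the methylation-silenced and imprinted genes had the lowest camera p. Of the 15 genes on this list, 3 were measured. QQS and AT2G04770, the latter read by an _x_at probe set, rose in both lines. The maternally expressed gene MPC had a change of 0.10 ± 0.22 in line774 and 0.07 ± 0.22 in line1135. The same 2 of 3 passed when adjusted over the list alone. The camera test gave an adjusted p of 5.43e-05 in each line, and adjusted p = 0.0636 with an estimated correlation.

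Of the 22 listed cold, drought and abscisic acid genes, 3 were measured, and COR15A was called lower in both lines. COR47, a dehydrin, had changes of -0.46 ± 0.12 and -0.40 ± 0.12, and COR15B of -0.43 ± 0.23 and -0.18 ± 0.23. At any fold, 2 of 3 passed in each line, both over all probe sets and adjusted over the list alone. The list was lower by camera with adjusted p = 0.0304 in line774 and 0.0459 in line1135, and adjusted p = 0.354 with an estimated correlation in both. With the replicate number as a block, camera gave adjusted p = 0.0394 in line774 and 0.0586 in line1135, so the latter call was lost. Of the 21 listed cell cycle genes, 3 were measured, and AUR1 and AUR2, Aurora kinases, were higher in both lines at less than 2-fold. PRL, a subunit of the replicative helicase, had changes of 0.18 ± 0.12 in line774 and 0.48 ± 0.12 in line1135. AUR1 changed by 0.54 ± 0.11 in line774 and 0.45 ± 0.11 in line1135, AUR2 by 0.60 ± 0.13 and 0.70 ± 0.13. At any fold, 2 of 3 passed in line774 and 3 of 3 in line1135, both over all probe sets and adjusted over the list alone. Camera gave adjusted p = 0.0442 and 0.0147, and adjusted p = 0.32 and 0.223 with an estimated correlation. The replicate number as a block gave camera adjusted p = 0.0586 in line774, where the call was lost, and 0.0256 in line1135.

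Of the 22 listed flavonoid and anthocyanin genes, 6 were measured. All 6 had negative differences between line1135 and line774, and 0 were called at 2-fold (median -0.32, camera adjusted p = 0.00545, and adjusted p = 0.222 with an estimated correlation). DFR, the dihydroflavonol reductase, differed by -0.71 ± 0.15 (adjusted p = 0.0377), the only member passing at any fold over all probe sets, against 3 adjusted over the list alone. UGT78D2 had a difference of -0.37 ± 0.11.

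The other lists had no member called at 2-fold in any comparison and no camera call, where one could be run. They were the methionine cycle (3 of 22 listed genes measured), salicylic acid (2 of 20), jasmonate (3 of 21), heat shock (4 of 18) and photosynthesis (5 of 26). Flowering (2 of 24), clock (1 of 16), root markers (2 of 20), senescence (1 of 13) and silencing regulators (1 of 39) were the rest. Most genes of each list were not among the probe sets named here, so no lack of change in these pathways can be read from them. The silencing regulator DME, a DNA demethylase, had a change of 0.07 ± 0.13 in line774. The root markers PYK10 and EXPA7 had changes of -0.23 ± 0.14 and 0.49 ± 0.16 in line774, and -0.12 ± 0.14 and 0.16 ± 0.16 in line1135. PRK, a Calvin cycle kinase, had a change of 0.29 ± 0.08 in line1135 (adjusted p = 0.0421). The lists for DNA damage and seed markers had 0 members among the probe sets named here. The ratio of 3' to 5' signal of GAPDH, a sign of RNA quality, was 0.992 ± 0.0107 in the control, 1.05 ± 0.0479 in line774 and 1.08 ± 0.00715 in line1135 (SD, n = 3), and that of actin 3.58 ± 0.560, 3.78 ± 0.391 and 3.74 ± 0.288.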

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

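The tests of the explanations weighed in this part were chosen after the results were seen. The iron list, with 8 of its 25 genes measured, was added after 3 of its members had been seen among the largest changes.

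The direct test between the 2 mutant lines singled out 3 counts. Among the 50 named probe sets, picked mostly for large changes, it called 23 transcripts of named genes and a probe set with no gene named here. Only these are listed below, not all calls of the test. Line1135 had 99 probe sets higher and 38 lower than line774, and 76 of those higher were of the pseudogene class. The transcripts higher in line1135 were AT1G59930 (4.71), AT1G36590 (3.25), AT1G36240 (2.84), AT4G08680 (2.77), AT2G05470 (2.68), AT3G47260 (2.67), AT2G24930 (2.63), AT2G14130 (2.61), AT2G06430 (2.59), AT3G32900 (2.58), SQN (2.26), AT4G03790 (1.92) and AT4G05640 (1.34), as log2 differences. Those of AT1G36590, AT4G08680, AT2G05470 and AT2G24930 depend on the offset, with line774 at or below background, and only bounds of at least 18.8-, 10.2-, 10.3- and 8.44-fold can be given. Those lower were AT1G20400 (-2.99), AT5G24240 (-2.66), AT4G33720 (-2.44), AT4G22490 (-2.36), AT3G16670 (-2.08), AT3G29970 (-1.61), AT3G61930 (-1.60), AT5G19890 (-1.50), AT3G13610 (-1.41) and OSM34 (-1.30). Of these, AT4G33720, AT3G29970, AT3G61930, AT5G19890, AT3G13610 and OSM34 each lost this call when some single array was left out. AT3G61930 was also called higher in line774 than in the control, a call lost without control replicate 1 (adjusted p = 0.0585), control replicate 3 (0.065) or line774 replicate 2 (0.0553), with adjusted p from 0.00141 to 0.121 over all alternatives. A probe set with no gene named here, chosen after its values were seen, had a difference of 2.81, with signals of 2346 ± 198 in the control, 432 ± 18.1 in line774 and 3119 ± 64.9 in line1135 (SD, n = 3).

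Pseudogene-class probe sets were called higher in both lines more often than other probe sets, although most of the class was not called and its camera call was lost with an estimated correlation (adjusted p = 0.606 in line774 and 0.198 in line1135). A single scaling factor per array cancels in the share of summed signal that the class takes, and the lowest share in a mutant array was 8.72 times the highest in a control array, which argues against such a factor. Probes shared between loci stay open, and a rise of the named locus cannot be told apart from that of a related copy. The odds ratio of 5.00 among _at probe sets, in the line where it was smaller, shows that the enrichment is not limited to _s_at and _x_at probe sets, but _at probes can also read copies that the design did not list. A loss of silencing in the mutant lines remains an untested hypothesis.

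More pseudogene-class probe sets were called higher in line1135 than in line774, 76 against 0 called lower (camera adjusted p = 7.92e-10, and adjusted p = 0.198 with an estimated correlation). Members with a line774 signal under 16 could not be called lower, so the count of 0 is partly set by the offset. With the filter at the 50th percentile of mean signal, the 2 lines had nearly the same number of the class called higher than in the control. Some of the class still differed between the lines there. The lowest share of summed signal in a line1135 array was 1.46 times the highest in a line774 array, which argues against a single scaling factor per array. Of the 76 called, 26 were _at and 50 _s_at or _x_at probe sets, and for both kinds the named locus cannot be told apart from related copies, which would also give higher calls. The 2 lines themselves, whose mutations are not named in the labels used here, remain an untested explanation.

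Iron deficiency transcripts were higher in line774, with 5 of 8 measured members called, among them AT1G47400, an iron-signalling peptide gene (3.63 ± 0.12), BHLH101 (at least 5.70-fold, with the control at or below background) and AT3G12900 (1.32 ± 0.16), and a list median of 1.37 (camera adjusted p = 2.44e-08, and adjusted p = 0.198 with an estimated correlation). In line1135, 1 of 8 was called, AT1G47400 (2.55 ± 0.12), with a list median of 0.32 (camera adjusted p = 0.0464, and adjusted p = 0.822 with an estimated correlation), and in the direct test 3 of 8, AT1G47400, AT3G61930 and AT3G13610, were lower in line1135 than in line774 (camera adjusted p = 5.26e-09, and adjusted p = 0.198 with an estimated correlation), though the last 2 both lost their calls without line774 replicate 2 (adjusted p = 0.137 and 0.0677) or line1135 replicate 1 (0.0931 and 0.0649). These camera tests included the 3 members seen first, whose median was 1.77 in line774. The list was added after these had been seen, so the camera p-values are no independent support. The 5 members not seen first all had positive changes in line774, from 0.47 to 1.42 (median 0.76), so the rise was not limited to the 3 seen first. An exact one-sided sign test gave p = 0.0312, the lowest it can give for 5 genes. It takes the genes as independent, which members of 1 response may not be, so no weight is put on it. A larger share of root tissue cannot be told apart by 2 root markers, since PYK10 reached 0.05 and EXPA7 0.81 at 2 standard errors above their changes, the latter above the median of those 5 members. A difference in plates or medium cannot be told apart from the lines, because the labels name no plate.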

How the results depend on the processing

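The pseudogene counts under all alternatives, and the setting without probe sets near background, were chosen after seeing the data. Of 242 alternative counts, 198 stayed within 1.5 times the value reported. At an offset of 1, the counts of probe sets higher and lower in line774 were 481 and 364, in line1135 501 and 490, lower in line1135 than in line774 71, and higher in both lines 271, with pseudogene-class counts of 142 and 232 for line774 and line1135. At an offset of 64 they were 102 and 107, 111 and 113, 48 and 13 between the lines, and 60 and 76 in both, with 44, 77 and 39 of the pseudogene class. The offset sets the fold of low signals by construction. With the filter at the 50th percentile, which tests fewer probe sets, the higher counts were 152 in line774, 110 in line1135, 35 between the lines and 84 in both, with 51, 52 and 23 of the pseudogene class. Most of the excess of the class in line1135 over line774 was thus in probe sets below that filter. Without cross-hybridising probe sets, again fewer, 146 were higher in line1135, 44 between the lines and 71 in both, with 27, 61 and 26 of the pseudogene class. With no minimum fold, the counts were 1502 and 1366 in line774, 1532 and 1560 in line1135, 256 and 198 between the lines, and 864 and 949 in both. At an adjusted p under 0.01, 17 were lower in line1135 than in line774.

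With each array left out in turn, the higher and lower counts ranged from 207 to 252 and 184 to 261 in line774, from 230 to 260 and 230 to 300 in line1135, from 95 to 104 and 22 to 48 between the lines, and from 123 to 146 and 129 to 176 in both lines. Pseudogene-class counts ranged from 83 to 93, 146 to 151 and 74 to 79. The cause of the drop to 22 was not tested beyond having fewer samples. Same-numbered arrays had deviations that correlated weakly, by 0.0274 to 0.0894, but the best match had its own number in 16 of 18 comparisons. A pairing by replicate number thus stays possible, a hint from the data only, and the main fit leaves it out. With the replicate number as a block, the counts were 235 and 226 in line774, 246 and 278 in line1135, 99 and 44 between the lines, and 136 and 162 in both. The block also moved camera's adjusted p to 0.0586 for the cell cycle list in line774 and for the cold list in line1135.

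Of 2120 alternative values of called results for 50 named probe sets, 2077 kept the call, 43 lost it and 0 changed sign, and of 799 alternative values of uncalled results 20 gained a call. These probe sets were picked mostly for large called changes, so this does not measure how stable all calls were. Of all calls in line774, an offset of 64 kept 102 of 233 higher and 107 of 223 lower. In line1135 it kept 111 of 242 and 113 of 278. Quantile normalization kept 219 of 233 and 221 of 223 in line774. Between the lines, leaving out line774 replicate 1 kept 92 of 99 higher and 19 of 38 lower. Under quantile normalization the median change of all probe sets lay between -0.000324 and 0.000126, and without it at most at 0.0216, so no scaling moved it by over 0.1. Signals near the Bacillus background limit what can be said of transcripts that are low in all groups.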

Other observations

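The families and the genes named in this part were chosen after the main comparisons had been seen. The tests of neighbouring genes and of other splits were set before their own results were seen.

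All 8 measured autophagy (ATG) genes, 7 of them coding for the ubiquitin-like protein ATG8 that is joined to autophagosome membranes, had negative changes in both lines, and 0 were called at 2-fold, while 3 of 8 passed at any fold in line774 and 5 of 8 in line1135. The median was -0.30 in line774 and -0.47 in line1135 (camera adjusted p = 0.00203 and 0.000157, and adjusted p = 0.628 and 0.474 with an estimated correlation). ATG8C had changes of -0.40 ± 0.08 and -0.54 ± 0.08, and ATG8F of -0.43 ± 0.07 and -0.41 ± 0.07. The sign of the median held under each scaling. The 10 measured expansins, wall-loosening proteins, had a median difference of -0.31 between line1135 and line774 (camera adjusted p = 0.00406, and adjusted p = 0.198 with an estimated correlation). Of the 10, 0 were called at 2-fold in that comparison and 1, EXPA4, passed at any fold (-0.77 ± 0.08). EXPA4 rose by 1.26 ± 0.08 in line774 and had a change of 0.48 ± 0.08 in line1135.

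The 69 plastid-encoded genes had a median change of -0.17 in line774 and a median difference of 0.21 between line1135 and line774 (camera adjusted p = 0.000144 and 7.15e-12, and adjusted p = 0.822 with an estimated correlation for both). At 2-fold limma called 0 of them, and at any fold 4 of the 69 passed in line774 and 2 between the lines over all probe sets, against 1 and 4 adjusted over the list alone. Among single members of other families, ALDH7B4, an aldehyde dehydrogenase, fell by 1.35 in line1135, with a standard error of 0.17. Its signal was 1506 ± 183 in the control, 771 ± 195 in line774, where it was not called, and 582 ± 80.6 in line1135 (SD, n = 3). LCR68, a defensin-like protein, changed by -1.16 ± 0.12 in line1135 and UGT85A5 by -1.05 ± 0.19 in line774 and -1.25 ± 0.19 in line1135. GH3.3, which joins auxin to amino acids, rose by 1.11 ± 0.16 in line1135.

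A hypothesis was that reactivation of a pseudogene-class locus may reach neighbouring protein-coding genes. In line1135, 2 of 96 protein-coding probe sets within 2 gene models of a called pseudogene-class locus were higher, AT5G28560 and AT3G31350, against 10 of 556 beside a measured and uncalled one. The odds ratio was 1.16 (95% interval 0.122 to 5.58, two-sided Fisher exact test, adjusted p = 1), too wide to decide. In line774 it was 0 of 53 against 8 of 599.

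Other splits of the arrays were counted for each comparison. For the 6 arrays of 2 groups there are 10 splits, too few for a share under 0.05. The real split was the 1 split with as many calls in every case. It gave 233 higher and 223 lower in line774, with 0 the highest of the other splits, 242 and 278 in line1135, again with 0, and 99 and 38 between the lines, with 1. For the pseudogene class it gave 87, 148 and 76, with 0 as the highest of the other splits. Of 100 splits of the 9 arrays into 3 groups, 3 gave as many as the real 133 higher in both lines and 3 as many as the real 160 lower, the real split included. Such counts were thus rare, and they register only whether the controls stay apart from the mutant arrays. The splits take the arrays as independent samples, which the labels do not state. A difference in culture or plates between control and mutant lines would give the same counts. Counts shared by both lines cannot test the parting of the mutant arrays into 2 lines. The highest of the other splits gave 137 and 174. In 2 of the other 99 splits the 3 controls stayed together with the mutant arrays mixed, and these held the highest counts, while the rest gave at most 6 higher and 53 lower.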
